A study of Mus musculus with 25 samples.

How the data were processed

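The series measured ribosome-associated messenger RNA of astrocytes from mouse thoracic spinal cord in 25 libraries, 1 per animal, that fall into 7 groups of 3 genotypes. Per the labels, ribosomes carried a haemagglutinin tag in cells expressing Gfap-Cre (RiboTag), and tagged ribosomes were precipitated with their RNA. Mice were wild type (WT), or lacked Stat3 (Stat3cKO) or Smarca4 (Smarca4cKO) in cells expressing Gfap-Cre. They were uninjured, studied 24 hours after an intraperitoneal injection of 5 mg/kg lipopolysaccharide (LPS), or, in Smarca4cKO only, studied 14 days after a complete crush spinal cord injury (SCI). The SCI tissue was the central 3 mm of the lesion with its core and 1 mm on either side. Libraries were made from 10 ng of RNA with an RNA integrity number of at least 8.9 and sequenced as paired reads of 50 bp. The groups were WT uninjured (4 libraries), WT LPS (4), Stat3cKO uninjured (3), Stat3cKO LPS (4), Smarca4cKO uninjured (3), Smarca4cKO LPS (3) and Smarca4cKO SCI (4). The labels give a mixed C57BL6;129S2 strain to the Smarca4cKO mice.

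The submitters' notes name STAR 2.4.0j, HTSeq 0.6.0, edgeR 3.28.0 and the mm10 genome, without saying what each did. The authors deposited 4 tables, each comparing a challenge with uninjured mice of the same genotype. Each table gives raw counts per gene and library as deposited by the authors. The authors' normalized counts are a signal in which each library is its raw count times 1 factor. The authors also deposited log2 fold changes, p-values and false discovery rates, the last equal to a Benjamini-Hochberg adjustment of their p-values. The tables hold 10568 genes (WT), 11712 (Stat3cKO), 8052 (Smarca4cKO LPS) and 11115 (Smarca4cKO SCI), so the authors had removed genes by a rule they do not state. Of 12454 genes in any table, 7834 are in all 4. Genes were matched by symbol, and positions come from GENCODE M21 (GRCm38), which gave a position for 11909 genes. Chromosome and strand were the same as in the tables for 11727 of them and differed for 5, and 22 symbols had been turned into dates.

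Raw counts were analysed with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by TMM, genes were kept by filterByExpr, and the quasi-likelihood test was used with a Benjamini-Hochberg adjusted p under 0.05. Each single comparison used only its own libraries. Differences between responses were tested as interaction terms in a fit of the 4 groups concerned, or the 3 groups for SCI minus LPS in Smarca4cKO, where both responses share the 3 uninjured libraries. No paired analysis was possible because the titles are animal numbers with no pairing, and the labels give no batch or sex. Levels are CPM, raw counts scaled to one common library total after TMM, given as mean ± SD, and log2 fold changes as estimate ± SE. Where a gene had 0 counts in all libraries of a group, the fold was computed against 3 counts over the group's summed total and is a bound. Where it had 1 to 3 counts, the ratio of rates is given with its 95% exact (Clopper-Pearson) counting interval. These bounds and intervals cover counting error only, since the reads carry no molecular identifiers.

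The design, the tests, the alternatives and a set of gene lists were fixed before the data were examined. The lists were pan-reactive, A1-type and A2-type astrocyte genes, interferon response, antigen presentation, cytokines and chemokines, NF-kB targets and regulators, STAT3 targets and IL-6 family signalling, complement and acute phase, glucocorticoid-responsive genes, astrocyte homeostatic genes, cholesterol and sterol synthesis, cell cycle and proliferation, extracellular matrix, reactivity-associated transcription factors, the BAF complex, heat shock and unfolded protein response, and axon growth and synapse-related genes. Marker lists covered microglia, monocytes and macrophages, neutrophils, T cells, B cells, oligodendrocytes and their progenitors, neurons, endothelial cells, pericytes and smooth muscle, fibroblasts and meninges, ependymal cells, Schwann cells, erythrocytes and sex-linked genes. Some genes are in more than 1 list. Lists with at least 3 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, then with an estimated correlation and with fry. For each list the count of genes past the threshold is given over all genes tested and, where stated, adjusted over the list alone.

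Genes named in the report follow a rule. For each single comparison these are the 5 largest rises and 5 largest falls past the threshold, among genes with non-overlapping groups and a mean of at least 1 CPM, without symbols of the Gm or Rik type. The rule adds from each functional list the 2 largest changes and up to 2 in the opposite direction, the most abundant member of each marker list, and 11 genes in every case: Stat3, Smarca4, Gfap, Vim, Lcn2, Serpina3n, Cxcl10, Socs3, C3, Aqp4 and Slc1a2. For differences between responses it takes 3 genes per direction and the same 11. Some genes that the rule names are not reported here.

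The alternatives were DESeq2 1.42.0, the edgeR likelihood ratio test, median-of-ratios scaling, no low-count filter, all libraries in one fit, a test against a fold change of 2, the authors' own FDR, an adjusted p under 0.01 for overlaps, the other list tests, and leaving out each library in turn. Robust quasi-likelihood, limma voom and a mean of at least 20 CPM were added after seeing the data. Alternatives meant for normalized values were not run, since the tables hold counts. The tests were tried on simulated data with negative binomial counts and 200 changed genes. Genes called by edgeR were false in 0% to 6.67% of cases over the 8 comparisons, and those called by DESeq2 in 27.6% to 59.5%. An 8-fold change was recovered by edgeR in 58% of genes for WT and for Stat3cKO LPS, 20% for Smarca4cKO LPS and 29% for Smarca4cKO SCI. The recovery of an 8-fold difference was 14% to 51% for the differences between responses. Many real genes were near all-or-none, which these simulations did not contain. Tables were read and drawn with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.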

Results

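The data are counts of ribosome-associated RNA of spinal cord astrocytes in 25 libraries from mice that were WT, Stat3cKO or Smarca4cKO, left uninjured, given LPS, or, for Smarca4cKO, given an SCI. The WT uninjured libraries 1 to 4 held 61911836, 91910322, 52433934 and 82394337 counts, and the WT LPS libraries 66344317, 76697108, 80527845 and 106308622. The Stat3cKO uninjured libraries 1 to 3 held 79169458, 67704531 and 91419161 counts, and the LPS libraries 1 to 4 held 62803836, 75500674, 76618408 and 86169202. The Smarca4cKO uninjured libraries 1 to 3 held 82318383, 67848962 and 75751796 counts in the deposited LPS table and 84753493, 69518976 and 77793594 in the SCI table, which lists more genes. The Smarca4cKO LPS libraries 1 to 3 held 64843911, 73709560 and 106513035 counts, and the SCI libraries 1 to 4 held 102544326, 74372083, 83291124 and 69717172. The share of listed genes with 10 counts or fewer was 17.8%, 25.7% and 21.2% in the uninjured Smarca4cKO libraries of the SCI table and at most 1.04% in the SCI libraries beside them. In the LPS table, which lists fewer genes, the same uninjured libraries had 4.82%, 9.17% and 6.28%. The share was 12.2%, 14.9% and 1.35% in the Smarca4cKO LPS libraries, and between 0.927% and 8.06% in the WT and Stat3cKO libraries. No pair of replicates looked like the same library sequenced again, since the chi-square per degree of freedom between replicates was 187 to 1918 over 36 pairs. No WT or Stat3cKO library after SCI is in the series.

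**Figure D1:**
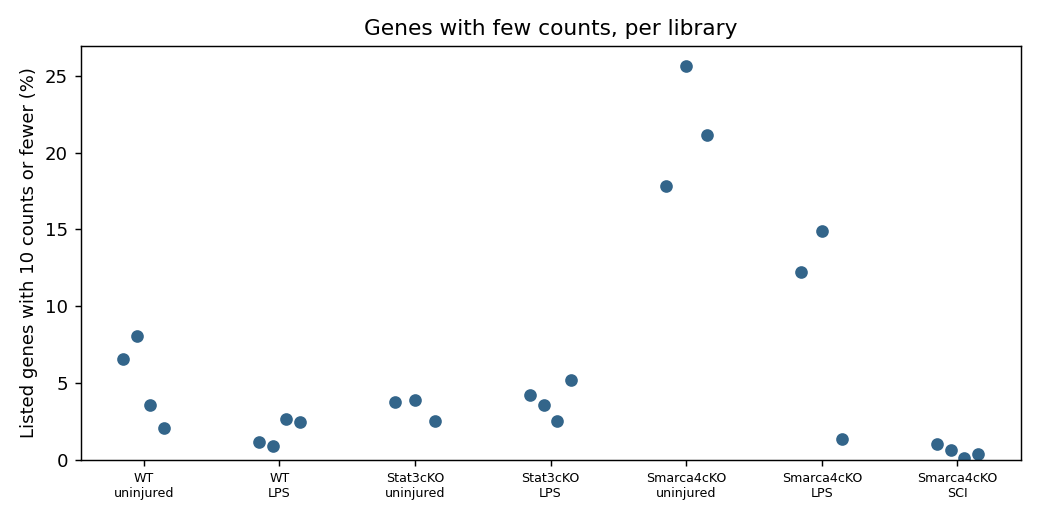
Percentage of listed genes with 10 counts or fewer in each library (points), by group. The uninjured Smarca4cKO libraries lie at 17.8% to 25.7% in the SCI table, against 0.0990% to 1.04% for the SCI libraries, and at 4.82% to 9.17% in the LPS table (not drawn).

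The targeted genes show what the deletions left. Stat3, the transcription factor downstream of IL-6 family cytokines (chromosome 11, 100885098 to 100939540, minus strand, GRCm38), had 8103, 8335, 7464 and 7982 counts in uninjured WT libraries and 707, 1347 and 741 in uninjured Stat3cKO libraries. Its means were 118 ± 26.6 CPM (SD, n = 4) and 12.1 ± 6.67 CPM (n = 3). After LPS it had 11066, 25679, 35753 and 30873 counts in WT (305 ± 129 CPM) and 17953, 8586, 6908 and 15784 in Stat3cKO (174 ± 94.7 CPM). This was a rise in Stat3cKO of log2 3.85 ± 0.51 (edgeR adjusted p = 0.00108), to 85.0 to 297 CPM in each library. Gene counts do not show which exons were read. Stat3 had 10497, 8759 and 4016 counts in uninjured Smarca4cKO libraries, 29635, 12362 and 18130 after LPS, and 29960, 18195, 16978 and 13003 after SCI. Smarca4, the ATPase of the BAF chromatin remodelling complex (chromosome 9, 21616169 to 21704230, plus strand), had 3384, 6129, 4404 and 7009 counts in uninjured WT libraries (74.0 ± 11.8 CPM) and 7759, 4731, 5653 and 7256 in WT LPS libraries (77.4 ± 25.2 CPM). In Stat3cKO it had 6074, 6460 and 8492 counts uninjured and 4577, 4254, 6597 and 6070 after LPS. It had 1132, 1592 and 1799 counts in uninjured Smarca4cKO libraries (20.4 ± 5.93 CPM, n = 3) and 2060, 898, 1879 and 1460 after SCI (18.5 ± 4.45 CPM, n = 4). The Smarca4cKO LPS libraries held 1, 3664 and 651 counts, and library 2 reached 50.9 CPM, close to the lowest WT library at 59.4 CPM. Levels of uninjured mice were not compared between genotypes by a test.

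**Figure D2:**
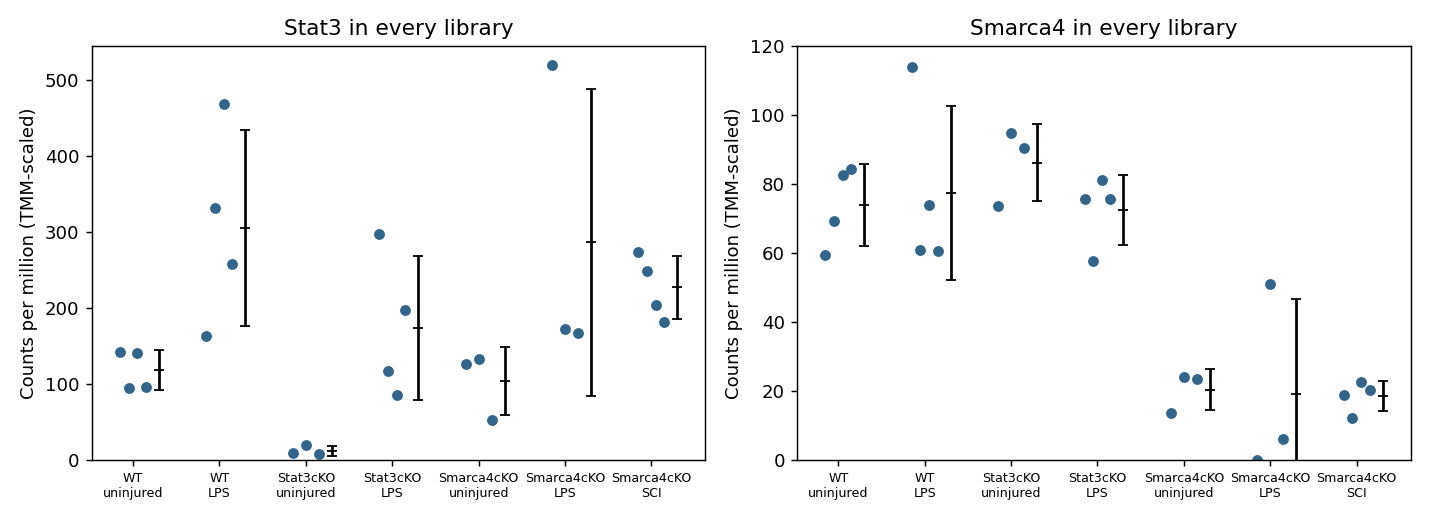
Level of Stat3 and of Smarca4 in CPM in each of the libraries (points), with the group mean and SD, for the 7 groups. Mean Stat3 is 12.1 CPM in uninjured Stat3cKO and 174 CPM in Stat3cKO after LPS, and Smarca4cKO LPS library 2 holds 50.9 CPM of Smarca4.

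The comparison of WT mice after LPS with uninjured WT mice asks what systemic inflammation does to astrocytes with both genes intact. Lcn2, a secreted lipocalin that binds bacterial iron carriers (chromosome 2, 32384633 to 32388252), rose from 0.140 ± 0.0494 to 756 ± 608 CPM (SD, n = 4 each), a log2 change of 12.37 ± 0.72 (SE, adjusted p = 4.79e-06). Serpina3n, a serine protease inhibitor (chromosome 12, 104406729 to 104414329), rose from 115 ± 57.6 to 4944 ± 2111 CPM (log2 5.43 ± 0.45, adjusted p = 0.000144). Among genes with 1 to 3 counts in the uninjured group, the ratios were 4036 for the metalloreductase Steap4 (95% counting interval 1117 to 33334), 3038 for serum amyloid Saa3 (1039 to 14733) and 3499 for Lrg1 (968 to 28899). Myoc fell by 4.49 ± 0.50 from 563 ± 102 CPM (adjusted p = 0.00133), and the lipid-binding protein Pmp2 to a ratio of 0.000360 (4.35e-05 to 0.00130). These calls, and those of Rsad2, H2-Q4, Plin4 and Hspb1, held without any 1 library.

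Genes of reactive astrocytes rose after LPS in WT. Of 13 pan-reactive genes 7 rose (10 adjusted over the list alone), among them the small heat shock protein Hspb1 (29.2 ± 19.6 to 979 ± 933 CPM), Timp1, an inhibitor of metalloproteinases (log2 6.59 ± 1.39), and the intermediate filament gene Vim (251 ± 85.7 to 517 ± 102 CPM, log2 1.04 ± 0.24, adjusted p = 0.0454). Gfap, the astrocyte filament gene, was at 18232 ± 2735 and 21417 ± 1889 CPM (log2 0.23 ± 0.14, adjusted p = 0.525). Of 10 A1-type genes 5 rose (10 over the list alone), with Amigo2 at log2 3.80 ± 0.74 and H2-T23, a class I MHC gene, at 4.69 ± 1.09. Of 8 A2-type genes 3 rose (4 over the list alone), with Tgm1 at 10.12 ± 1.68 and Clcf1, an IL-6 family cytokine, at a ratio of 1252 (224 to 49492). Complement and acute phase genes rose in 5 of 12 cases (6 over the list alone; adjusted p = 0.0095 with an estimated correlation), and the pan-reactive list kept its call in the same way (0.0175). The A1-type and A2-type lists lost theirs (adjusted p = 0.0509 and 0.207 with an estimated correlation). Calls lost without 1 library were those of Timp1 (up to adjusted p = 0.106, in 5 of 8 fits), Vim (0.140, 6 fits), Amigo2 (0.0981, 3 fits), H2-T23 (0.142, 7 fits), Clcf1 (0.0861, 5 fits) and Tgm1 (0.0663, without LPS 3 or uninjured 4). Library LPS 3 held 62.0 CPM of Tgm1 and the others 2.12 to 7.50.

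Interferon response genes rose in 7 of 28 cases in WT (20 adjusted over the list alone; median log2 2.51; adjusted p = 0.0395 with an estimated correlation). Rsad2, the antiviral protein viperin, went from 0.0401 to 17.6 ± 10.0 CPM (log2 8.70 ± 1.39, adjusted p = 0.0119), and the guanylate-binding GTPase gene Gbp5 rose by 8.95 ± 1.41. Gbp5 was at 110 CPM in LPS 3 and 3.25 to 13.9 CPM in the others, and its call was lost without LPS 3 (adjusted p = 0.0660). The T cell chemokine gene Cxcl10 was at 244 CPM in LPS 3 and 2.70 to 15.8 CPM in the others (log2 4.20 ± 1.24, adjusted p = 0.107). Antigen presentation genes rose in 4 of 14 cases (9 over the list alone), with H2-Q4 at 4.19 ± 0.63 (adjusted p = 0.207 for the list with an estimated correlation). Reactivity-associated transcription factors rose in 2 of 34 cases (8 over the list alone, 0.187), Stat3 by 1.37 ± 0.30 and the interferon regulatory factor gene Irf9 by 1.81 ± 0.39. Stat3 was the 1 gene past the threshold among 18 STAT3 target and IL-6 family genes (6 over the list alone, 0.117), and Socs3, which restrains this pathway, was at log2 5.49 ± 1.83 (adjusted p = 0.163). The glucocorticoid-responsive list had 3 rises of 22 (7 over the list alone, 0.241), with the lipid droplet gene Plin4 at 3.13 ± 0.49 and the cell cycle inhibitor gene Cdkn1a at 2.60 ± 0.55. Stat3, Irf9 and Cdkn1a lost their calls in 7, 7 and 4 of 8 fits without 1 library (adjusted p up to 0.112, 0.0921 and 0.105).

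Genes of resting astrocytes fell in WT after LPS: 5 of 35 homeostatic genes (11 lower and 1 higher over the list alone; adjusted p = 0.273 with an estimated correlation). The water channel gene Aqp4 went from 3303 ± 790 to 1810 ± 121 CPM (log2 -0.87 ± 0.18), Fabp7 from 160 ± 35.5 to 60.8 CPM (-1.39 ± 0.25) and the neurotensin receptor gene Ntsr2 from 2087 ± 394 to 1071 ± 222 CPM (-0.96 ± 0.19). The glutamate transporter gene Slc1a2 was at log2 -0.06 (adjusted p = 0.94) and complement C3 at 0.18 (0.857). In cholesterol synthesis, Dhcr7 fell by 1.15 ± 0.26, the 1 of 23 genes past the threshold (4 over the list alone, 0.241). The extracellular matrix list had 3 rises and 2 falls of 34 (adjusted p = 0.984), with Col4a2 up by 1.81 ± 0.39, Col1a1 down (log2 -2.31 ± 0.54) and the proteoglycan gene Ncan down (-0.99 ± 0.18). Without 1 library, calls were lost for Aqp4 (6 of 8 fits, up to adjusted p = 0.0981), Fabp7 (3, 0.0705), Ntsr2 (5, 0.0876), Dhcr7 (6, 0.122), Col4a2 (8, 0.0987), Col1a1 (7, 0.211) and Ncan (4, 0.0723). Other lists of the WT comparison did not pass camera: cytokines and chemokines (1 of 6 rose, Cxcl12 by 2.33 ± 0.51, lost in 6 fits, up to 0.136; list 0.149), NF-kB (0 of 14, 0.0571), cell cycle (0 of 9, 0.584), BAF complex (0 of 24, 0.475), heat shock (1 of 21, 0.984) and axon growth (0 of 15, 0.475). The heat shock list had a median log2 of -0.08 and a mean of 0.27, and its test pointed up.

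Markers of other cells in WT moved as follows. Oligodendrocyte markers pointed down by camera (adjusted p = 0.00788; 0 of 14 past the threshold; adjusted p = 0.442 with an estimated correlation), as did progenitor markers (0.0117; 0 of 8, 0.273), and neuron markers pointed up (0.0117; 0 of 15, 0.187). Those 3 calls were lost without LPS 2 (oligodendrocyte, 0.138), LPS 3 (progenitor and neuron, 0.0521 each) and uninjured 4 (0.0515, 0.0766 and 0.0515). The myelin gene Mbp was at 2274 ± 434 and 3951 ± 1422 CPM (log2 0.80, adjusted p = 0.126), against the direction of its list. The other marker lists did not pass: microglia (0 of 5; median log2 0.07, test pointing down, 0.984), macrophage (0 of 3, 0.181), pericyte (0 of 4, 0.109), fibroblast (1 fall of 6, 0.181), ependymal (0 of 8, 0.984) and Schwann cell (1 fall of 7; median 0.23, mean -1.40; 0.618). Neutrophil, T cell, B cell and erythrocyte lists had fewer than 3 genes in every table and were not tested.

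In all, 163 genes rose and 105 fell of 10566 tested in WT after LPS, and 1458 had an unadjusted p under 0.05. Groups did not overlap in 266 of the 268 called genes, and in 11.2% of all tested genes, where chance gives 2.86%. Other genes with the largest changes were Galr3, Mustn1, Dusp4 and Hrct1, at least 718-fold, 585-fold, 583-fold and 565-fold higher, and Rdh12 and Senp8, at least 875-fold and 853-fold lower. The receptor gene Aplnr fell by 2.57 ± 0.49. Each of these 7 lost its call without 1 library or more (highest adjusted p between 0.0638 for Rdh12 and 0.147 for Hrct1). The count was 217 at most when 1 library was left out, and was 29, 176 and 122 without LPS 2, 3 and 4, and 141, 58 and 68 without uninjured 1, 3 and 4. Of 36 named genes past the threshold, 27, 13, 22 and 20 kept it without LPS 1 to 4, and 24, 30, 13 and 14 without uninjured 1 to 4.

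Stat3cKO mice after LPS were compared with uninjured ones. Interferon response genes rose in 32 of 33 cases (median log2 6.81; adjusted p = 0.00264 with an estimated correlation). Members with few uninjured counts enter LPS lists only by counts after LPS, so list results partly follow from filters. Ifi44 went from 0.0182 to 238 ± 119 CPM (log2 13.68 ± 0.75, adjusted p = 3.58e-06) and Ifit1, which binds foreign RNA, from 0.0316 ± 0.0207 to 305 ± 234 CPM (13.13 ± 1.09, adjusted p = 5.15e-05). Cxcl10 (chromosome 5, 92346638 to 92348889) went from 0.475 ± 0.224 to 4115 ± 3508 CPM (13.10 ± 1.11, adjusted p = 5.46e-05; n = 3 and 4, edgeR). The largest rises also held Ifi47 (13.41 ± 0.96) and 3 genes with 0 counts in every uninjured library: AA619741, Mlkl and Gbp4, at least 2666-fold, 1726-fold and 1327-fold higher. All these calls held without any 1 library.

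Other lists in Stat3cKO after LPS were as follows. Antigen presentation genes rose in 15 of 19 cases (16 adjusted over the list alone; adjusted p = 0.0126 with an estimated correlation), with the class II gene H2-Aa at least 1319-fold higher and H2-T23 at log2 8.52 ± 1.41. Of 10 A1-type genes 9 rose (9 over the list alone, 0.00264), with the GTPase gene Iigp1 at 9.10 ± 0.97. Of 10 cytokine and chemokine genes 5 rose (6 over the list alone, 0.0162), with the monocyte chemokine gene Ccl2 at 12.82 ± 2.17. Of 13 complement and acute phase genes 7 rose (11 over the list alone, 0.0423), with Saa3 at a ratio of 8263 (2287 to 68237). Glucocorticoid-responsive genes rose in 16 of 22 cases (18 over the list alone, 0.0126), with Cdkn1a at 3.63 ± 0.39 and Map3k6 at 5.47 ± 1.48. Reactivity-associated transcription factors had 20 rises and 1 fall of 38 (26 and 1 over the list alone; adjusted p = 0.0931 with an estimated correlation). Fosl1, an AP-1 subunit gene, was at least 1171-fold higher and the interferon regulator gene Irf7 rose by 8.17 ± 1.21. STAT3 target and IL-6 family genes had 7 rises and 2 falls of 16 (10 and 2 over the list alone, 0.175). In that list the oncostatin M receptor gene Osmr rose by 10.11 ± 0.85, Junb by 5.05 ± 1.02 and Socs3 by 4.47 ± 1.25, and Hif1a and the shared receptor gene Il6st fell (-0.97 ± 0.17 and -0.80 ± 0.19). NF-kB genes rose in 4 of 16 cases (6 over the list alone, 0.358), with the adhesion gene Icam1 at 8.89 ± 1.41 and Nfkbiz at 4.47 ± 0.92, and A2-type genes in 1 of 7 (1 over the list alone, 0.224), with Sphk1 at a ratio of 3334 (923 to 27536). The A2-type list lost its camera call without LPS 1 and without LPS 4 (0.0713 and 0.0565). Calls lost without 1 library were those of Map3k6 (6 of 7 fits, up to 0.0839), Socs3 (6, 0.156), Il6st (without each uninjured library, 0.0995) and Nfkbiz (without uninjured 2 or 3, 0.0557). Beside these lists, 1 of 5 macrophage markers rose, Cd68 (log2 8.65, to 7.49 CPM), and among 4 microglia markers Olfml3 rose (3.47, to 42.4 CPM) and Sall1 fell (-1.02, to 45.9 CPM; lost in 6 fits, up to 0.163). Cd68 and Olfml3 were named after their values were seen.

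Pan-reactive genes rose in 9 of 13 cases in Stat3cKO (9 adjusted over the list alone; adjusted p = 0.00877 with an estimated correlation). Lcn2 rose from 0.400 ± 0.512 to 72.6 ± 45.2 CPM (log2 7.46 ± 0.96), Serpina3n from 39.0 ± 7.38 to 255 ± 65.2 CPM (2.71 ± 0.25), Gfap from 4954 ± 238 to 9735 ± 889 CPM (0.97 ± 0.09, adjusted p = 0.000147), and Steap4 to a ratio of 1951 (540 to 16112). Vim was at 153 ± 16.7 and 205 ± 37.9 CPM (0.42, adjusted p = 0.192) and C3 at 66.7 and 166 CPM (1.32, 0.0615). Homeostatic genes had 3 rises and 9 falls of 35 (5 and 15 over the list alone, 0.393). The gap junction gene Gja1 fell from 3062 ± 142 to 1330 ± 245 CPM (-1.20 ± 0.14) and Aqp4 from 3625 ± 212 to 1493 ± 354 CPM (-1.28 ± 0.17), while S100b rose by 0.83 ± 0.11 and glutamine synthetase Glul by 0.79 ± 0.10. Slc1a2 was at -0.27 (0.0827). Cholesterol synthesis genes fell in 6 of 23 cases (13 over the list alone, 0.175), with Dhcr7 at -1.44 ± 0.29. Extracellular matrix genes had 4 rises and 3 falls of 36 (median log2 -0.26, mean 0.04; adjusted p = 0.6), with Timp1 (6.20 ± 1.40) and Fbln5 (2.28 ± 0.38) up and Plod2 (-2.08 ± 0.44) and Ncan (-1.10 ± 0.28) down. Without 1 library, calls were lost for Dhcr7 and Plod2 (uninjured 1; 0.0599 and 0.0697), Timp1 (LPS 2 and uninjured 1, up to 0.0583) and Ncan (6 of 7 fits, up to 0.128).

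The last lists of Stat3cKO were these. The BAF complex had 2 rises of 24 (adjusted p = 0.941), Dpf2 by 0.78 ± 0.19 and Smarca2, the paralog of Smarca4, by 0.77 ± 0.19. The heat shock list had 2 rises and 1 fall of 24 (median -0.15, mean 0.10, test pointing down; 0.982), with Hspb1 at 4.41 ± 0.43, Atf4 higher (adjusted p = 0.000687) and Hspa8 at -1.24 ± 0.23. Axon growth had 1 rise of 17 (Ntn1, 0.66 ± 0.18; list 0.566) and the cell cycle list 0 of 13 (0.6). Markers of oligodendrocyte progenitors fell in 2 of 8 cases (adjusted p = 0.0931 with an estimated correlation), neuron markers rose in 4 of 15 (6 over the list alone, 0.13) and macrophage markers in 1 of 5 (0.129). Mbp rose from 1876 ± 324 to 4752 ± 694 CPM (1.34 ± 0.15), 1 of 2 rises beside 1 fall among 14 oligodendrocyte markers (0.98). Other marker lists did not pass: microglia (1 rise and 1 fall of 4; median 0.30, test pointing down; 0.941), endothelial (0 of 4, 0.305), pericyte (0 of 4, 0.98), fibroblast (1 fall of 6, Col1a2, -0.69 ± 0.18; 0.373), ependymal (1 rise of 9; median -0.49, mean 0.06; 0.98), Schwann cell (0 of 7, 0.314) and sex-linked (0 of 4, 0.6). Without 1 library, calls were lost for Dpf2 (3 of 7 fits, up to 0.0936), Smarca2 (3, 0.122), Ntn1 (6, 0.164) and Col1a2 (5, 0.150).

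In all, 834 genes rose and 403 fell of 11709 tested in Stat3cKO after LPS, and 2826 had an unadjusted p under 0.05. Groups did not overlap in 1232 of the 1237 called genes and in 27.3% of all tested genes, where chance gives 5.71%. The largest falls were those of Akap14, Htr5b, Slc16a13 and Adat1, at least 444-fold, 388-fold, 382-fold and 324-fold lower, and of Hes5, a Notch target gene, with a ratio of 0.000271 (6.85e-06 to 0.00151). Of these Hes5 alone held without any 1 library, and Akap14, Htr5b, Slc16a13 and Adat1 reached adjusted p = 0.0604, 0.0680, 0.0766 and 0.0761. The count of called genes was 657, 748 and 692 without uninjured 1, 2 and 3. Of 54 named genes past the threshold, 47, 47, 51 and 50 kept it without LPS 1 to 4, and 39, 42 and 43 without uninjured 1 to 3.

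The comparison of Smarca4cKO mice after LPS with uninjured Smarca4cKO mice asks how astrocytes respond with this deletion, although LPS library 2 held 50.9 CPM of Smarca4. Here 2 genes passed the test. Lcn2 rose from 0.224 ± 0.0646 to 805 ± 142 CPM (log2 11.81 ± 0.41, adjusted p = 2.19e-05; n = 3 each, edgeR) and Serpina3n from 298 ± 39.3 to 4537 ± 497 CPM (3.93 ± 0.19, adjusted p = 0.000148). Both held without any 1 library. Gfap was at 14662 ± 513 and 25257 ± 2355 CPM (0.78 ± 0.12, adjusted p = 0.0978), Vim at log2 1.22 ± 0.24 (0.2), Stat3 at 1.53 ± 0.55 (0.606), C3 at 0.51 (0.998), Aqp4 at -0.39 ± 0.15 (0.653), Slc1a2 at 0.15 (0.998) and Smarca4 at -0.03 ± 1.99 (0.999). Cxcl10 and Socs3 were not among the tested genes.

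Pan-reactive genes rose in 2 of 12 cases in Smarca4cKO after LPS, and in 9 adjusted over the list alone (median log2 3.59; adjusted p = 0.00341 with an estimated correlation). A1-type genes had 0 of 9 past the threshold over all genes tested and 4 over the list alone (median 3.42; 0.0463). A further 12 lists passed camera at the preset correlation and lost the call with an estimated one, each with 0 genes past the threshold over all genes tested. The adjusted p with an estimated correlation was 0.159 for A2-type genes (2 of 5 over the list alone), 0.174 for interferon response (3 of 17), 0.134 for antigen presentation (6 of 11) and 0.174 for complement and acute phase (3 of 7). For the STAT3 target and glucocorticoid-responsive lists it was 0.174 each (1 of 13 and 4 of 22), for NF-kB 0.255 (0 of 9), for reactivity-associated transcription factors 0.239 (0 of 27) and for cholesterol synthesis, which pointed down, 0.209 (0 of 22). Among markers it was 0.302 for oligodendrocyte progenitors, pointing down (2 of 7), 0.174 for pericytes (1 of 3) and 0.193 for ependymal cells (1 of 3). Lists that did not pass camera were cytokines (0 of 7, 0.158), homeostatic (0 of 35; median log2 0.03, mean -0.06; 0.973), cell cycle (0 of 4, 0.983), extracellular matrix (0 of 22, 0.547), BAF complex (0 of 23, 0.837), heat shock (0 of 22, 0.0597) and axon growth (0 of 12, 0.829). Marker lists that did not pass were oligodendrocyte (0 of 13, 0.0597), neuron (0 of 12, 0.408), fibroblast (0 of 4, 0.699) and Schwann cell (0 of 5, 0.181). Camera calls were lost without uninjured 2 and 3 and LPS 2 and 3 for ependymal cells (0.0573, 0.0675, 0.0912 and 0.128), without LPS 1 for NF-kB, transcription factors and progenitors (0.105, 0.114 and 0.177), and without LPS 3 for cholesterol synthesis (0.0829).

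Of 8040 genes tested in Smarca4cKO after LPS, 468 had an unadjusted p under 0.05, and other tests called more: 288 by DESeq2, 149 by the likelihood ratio test, 278 with all libraries in one fit, 73 by limma voom and 6 by robust quasi-likelihood. The authors' FDR called 174. Groups did not overlap in 17.0% of genes, where chance gives 10%. The biological coefficient of variation was 1.11, against 0.717 in WT and 0.661 in Stat3cKO. Without LPS 1 the count was 5.

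The comparison of Smarca4cKO mice 14 days after SCI with uninjured Smarca4cKO mice asks what a lesion does to astrocytes with this deletion. Smarca4 reads were still present, at a mean of 20.4 CPM uninjured and 18.5 CPM after SCI. Pan-reactive genes rose in 11 of 13 cases: Lcn2 from 0.236 to 325 ± 165 CPM (log2 10.43 ± 0.74, adjusted p = 0.00069), Serpina3n from 312 ± 45.9 to 3496 ± 665 CPM (3.49 ± 0.22), Vim by 2.25 ± 0.19 and Osmr from 0.0377 to 91.5 ± 12.3 CPM. Homeostatic genes fell in 23 of 35 cases, among them the GABA transporter gene Slc6a11 (4678 ± 294 to 1017 ± 343 CPM, -2.20 ± 0.28) and Slc1a2 (11644 ± 1186 to 4374 ± 1229 CPM, -1.41 ± 0.25, adjusted p = 0.00655). The homeostatic list lost its call with an estimated correlation (adjusted p = 0.101), and oligodendrocyte markers rose in 8 of 14 cases in the same libraries. Cholesterol synthesis genes fell in 15 of 23 cases, with Insig1 from 382 ± 132 to 43.3 ± 17.6 CPM (-3.14 ± 0.36). Genes of cell division rose in 14 of 25 cases, with Top2a, a DNA topoisomerase, at 27.0 ± 13.5 CPM and at least 2037-fold higher. A gene with few counts in the uninjured libraries is tested only if it has counts after SCI, so such genes can show only a rise. Anxa3 (chromosome 5, 96793339 to 96845966) had 0 counts in all uninjured libraries and 98.5 ± 17.9 CPM after SCI, at least 7429-fold higher (n = 3 and 4).

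Many of the rises after SCI started from few counts. Of the 1127 genes called higher, 828 had 10 counts or fewer in every uninjured Smarca4cKO library. Besides Anxa3 the largest rises were those of Col2a1 (at least 4322-fold), Fam101a (3979-fold), Ngfr (3352-fold) and Gpx8 (3240-fold). These bounds cover counting error, not loss from uninjured libraries, and Gpx8 was read in uninjured WT. The cell cycle list had a median log2 of 9.77, or 8.68 with genes at 0 counts set at their bound (adjusted p = 0.0326 with an estimated correlation, 14 over the list alone), and Cdk1 was at least 818-fold higher. Members with few uninjured counts entered the SCI lists only by counts after SCI, so counts, medians and tests are partly fixed by the filters. Extracellular matrix genes had 14 rises and 3 falls of 46 (18 and 3 adjusted over the list alone; adjusted p = 0.0861 with an estimated correlation). In that list the collagen gene Col11a1 was at least 2659-fold higher and the metalloproteinase gene Mmp2 had a ratio of 6989 (1935 to 57715). The proteoglycan gene Bcan fell by 1.60 ± 0.16 and the synapse-organising gene Sparcl1 by 1.88 ± 0.19. The fibroblast, ependymal, pericyte, Schwann cell and oligodendrocyte markers given further on pointed up in the same libraries.

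In the immune lists after SCI, genes rose beside microglia markers (4 of 10) and macrophage markers (2 of 8) in the same libraries. A1-type genes rose in 5 of 10 cases (5 adjusted over the list alone; adjusted p = 0.0373 with an estimated correlation), with the immunoproteasome gene Psmb8 at a ratio of 2611 (723 to 21566) and Srgn at 1042 (288 to 8612). A2-type genes rose in 4 of 8 cases (5 over the list alone, 0.0369), with the pentraxin gene Ptx3 at 6360 (2176 to 30844) and Clcf1 at least 360-fold higher. Complement and acute phase genes rose in 8 of 12 cases (8 over the list alone, 0.0373), with C1rl at least 528-fold and Lrg1 at least 412-fold higher, and C3 went from 493 ± 54.1 to 1040 ± 161 CPM. Transcription factors had 16 rises and 1 fall of 41 (17 and 1 over the list alone, 0.0321), with Egr1 at a ratio of 10834 (1944 to 427963), Runx1 at least 902-fold higher and Hif1a lower (log2 -0.83). The next lists passed camera only at the preset correlation. Interferon response genes rose in 11 of 29 cases (11 over the list alone; adjusted p = 0.101 with an estimated correlation), with Irf8 at least 885-fold higher and Isg15 at a ratio of 8272 (1484 to 326752). Antigen presentation genes rose in 5 of 17 cases (0.121), with H2-Aa at 1130 (203 to 44653). Cytokines and chemokines had 6 rises and 1 fall of 11 (median log2 10.10, or 9.27 at the bound; 0.0651). Cxcl16 was at least 1261-fold and the IL-6 family cytokine gene Lif at least 619-fold higher, Cxcl10 rose by 10.73 ± 1.01 and Il33 fell (-0.75). Glucocorticoid-responsive genes fell in 2 of 20 cases, Tsc22d3 by 2.21 ± 0.29 and Gjb6 by 1.64 ± 0.19 (0.163). The STAT3 target list (3 rises, 1 fall of 17, 0.0648), NF-kB list (3 rises of 16, 0.142) and axon growth list (4 rises, 2 falls of 20, 0.287) did not pass camera. Their members included Socs3 at 8902 (1597 to 351618), Icam1 at 4146 (1148 to 34242), Birc3 at 1544 (277 to 61028) and Plxnb1 lower (-0.56). Calls were lost without 1 library for Hif1a (4 of 7 fits, up to 0.106), Il33 (5, 0.0964), Plxnb1 (5, 0.131) and the glucocorticoid list (uninjured 2, 0.0619).

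Among structural and metabolic genes after SCI, Gfap went from 15305 ± 224 to 23112 ± 2988 CPM (log2 0.59 ± 0.17, adjusted p = 0.0492), a call lost in 6 of 7 fits without 1 library (up to 0.127). The pan-reactive list had 12 rises over the list alone (adjusted p = 0.0296 with an estimated correlation), with Steap4 at least 1853-fold higher. The homeostatic list had 26 falls and 3 rises over the list alone (0.101), with the amino acid transporter gene Slc7a10 at -2.04 ± 0.23, and Aqp4 was at 0.39 (adjusted p = 0.115). The cholesterol list had 18 falls over the list alone (0.0296), with Fdps at -2.27 ± 0.40. The heat shock list had 1 rise and 1 fall of 23 (median -0.07, mean 0.21, test pointing down; 0.525), Hspb1 by 4.10 ± 0.61 and Canx by -0.61. The BAF complex had 1 fall of 24 (median 0.05, test pointing down; 0.299), Smarca2 by 0.90 ± 0.21, a call lost without SCI 4 and without uninjured 2 (up to 0.0694). Stat3 was at 1.13 ± 0.33 (0.0621) and Smarca4 at -0.14 (0.979). The largest falls were those of Ppih, at a ratio of 0.00156 (0.000321 to 0.00457), Vegfa, the vascular growth factor gene (173 ± 57.1 to 17.7 ± 9.67 CPM, -3.29 ± 0.52), Insig1, Heyl (-2.99 ± 0.40) and Proca1 (-2.94, lost without SCI 2 and without SCI 3, up to 0.0837).

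**Figure D3:**
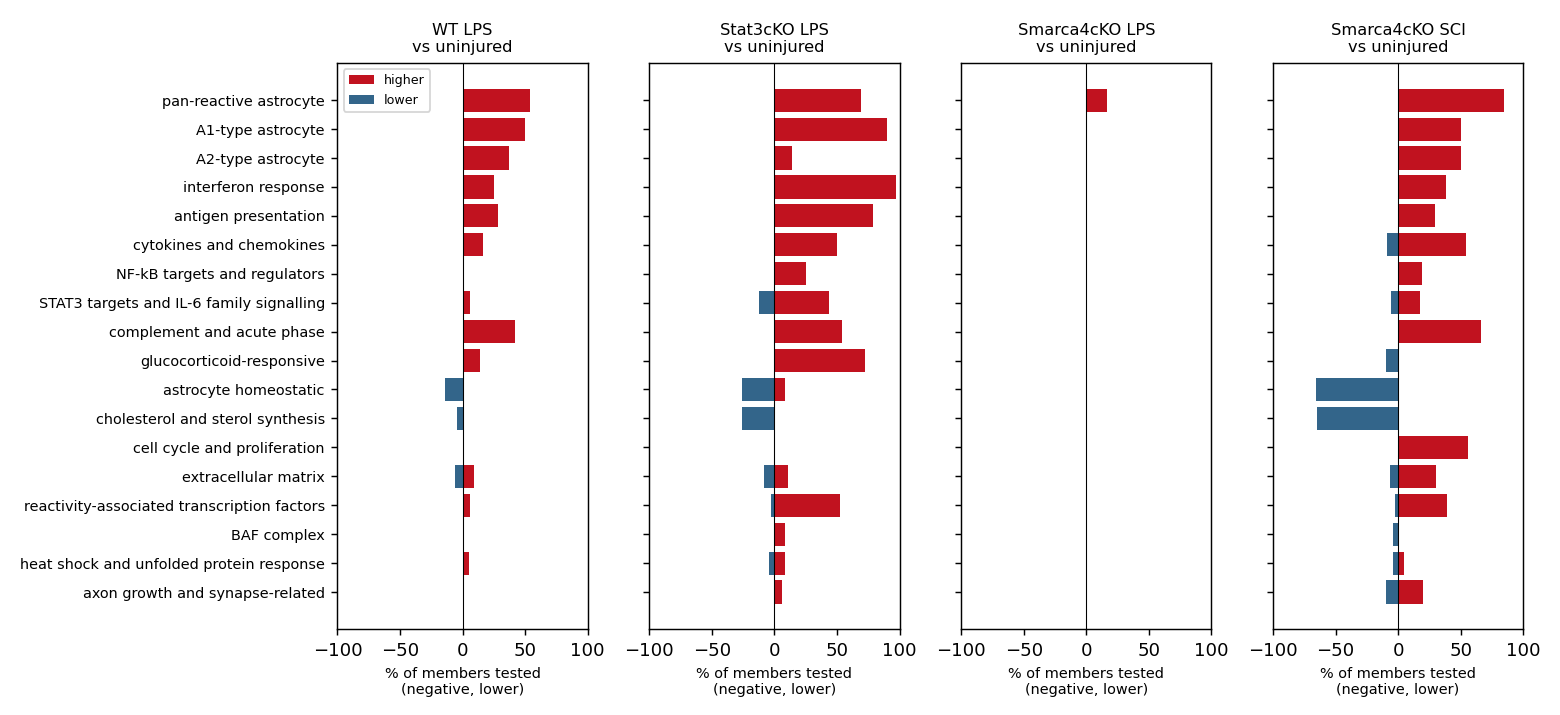
Percentage of tested members of each gene list that were called higher (to the right) or lower (to the left, as negative values) against uninjured mice, for the 4 challenge comparisons. Interferon genes rose in 32 of 33 cases in Stat3cKO after LPS, and homeostatic genes fell in 23 of 35 after SCI in Smarca4cKO.

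Markers of other cells after SCI pointed up in most lists. Oligodendrocyte markers rose in 8 of 14 cases (9 over the list alone; adjusted p = 0.104 with an estimated correlation), with Mbp from 4482 ± 1494 to 18013 ± 2673 CPM (log2 2.01 ± 0.26). Ependymal markers rose in 4 of 7 cases (median log2 8.37; 0.0373), fibroblast markers in 4 of 9 (6 over the list alone, 0.101), microglia markers in 4 of 10 (0.209), macrophage markers in 2 of 8 (0.196), pericyte markers in 3 of 6 (median 7.66, or 6.79 at the bound; 0.2), Schwann cell markers in 3 of 8 (0.244), and progenitor markers in 2 of 8 (3 over the list alone, 0.122). Endothelial markers rose in 2 of 3 cases (median 9.94, or 8.06 at the bound; camera 0.0715), and neuron markers had 1 rise and 1 fall of 12 (0.142), with Thy1 at 1.05 ± 0.15. The most abundant markers of these other lists did not pass: Gpnmb 4.51 (macrophage), Olig1 -0.33 (progenitor), Pecam1 -1.44 (endothelial), Tagln 5.12 (pericyte), Col1a2 0.63 (fibroblast) and Foxj1 1.20 (ependymal). Camera calls were lost without uninjured 2 and 3 for progenitors (0.0539 and 0.0649) and Schwann cells (0.0523 and 0.124), and without uninjured 3 for microglia (0.0532) and pericytes (0.0649).

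In all, 1127 genes rose and 479 fell of 11109 tested after SCI, and 2487 had an unadjusted p under 0.05. Groups did not overlap in 1603 of the 1606 called genes and in 28.5% of all tested genes, where chance gives 5.71%. The share of calls that were rises was 70.2%, and was 44.9% (768 calls) with all libraries in one fit, which holds only genes listed in every table, and 43.2% (655 calls) among genes with a mean of at least 20 CPM. Of 56 named genes past the threshold, 51 to 54 kept it without 1 library.

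The difference between the LPS responses of Stat3cKO and WT asks which changes depend on Stat3. Interferon response genes rose more in Stat3cKO: 9 of 28 passed the test of the difference (20 adjusted over the list alone; median difference log2 3.53; adjusted p = 0.000454 with an estimated correlation). The difference was 10.08 ± 1.18 for Ifit1 (adjusted p = 0.000995), 10.11 ± 2.02 for Ifi44 (0.033) and 8.86 ± 1.78 for Cxcl10 (0.033). Antigen presentation genes also rose more (3 of 14; 13 over the list alone, 0.0108), as did the A1-type list (0 of 9 singly; 6 over the list alone, 0.0241). Lcn2 and Serpina3n rose less in Stat3cKO, by log2 -4.95 ± 1.00 (adjusted p = 0.0334) and -2.75 ± 0.49 (0.0196). The difference was not past the threshold for Gfap (0.72, 0.0745), Stat3 (2.45, 0.0739), Vim (-0.65, 0.555), Socs3 (-1.05, 0.946), C3 (1.11, 0.476), Aqp4 (-0.44, 0.683), Slc1a2 (-0.24, 0.772) and Smarca4 (-0.34, 0.87). Without 1 library, calls were lost for Ifi44 (8 of 15 fits, up to 0.159), Cxcl10 (8, 0.159), Lcn2 (10, 0.407) and Serpina3n (without Stat3cKO LPS 1 and without Stat3cKO uninjured 1, up to 0.0549). Ifit1 held there, but limma voom kept 0 of the 8 named calls (Ifit1 at adjusted p = 0.636), robust quasi-likelihood kept 2, and all libraries in one fit kept 1 of the 3 it tested, Ifit1 not among them.

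**Figure D4:**
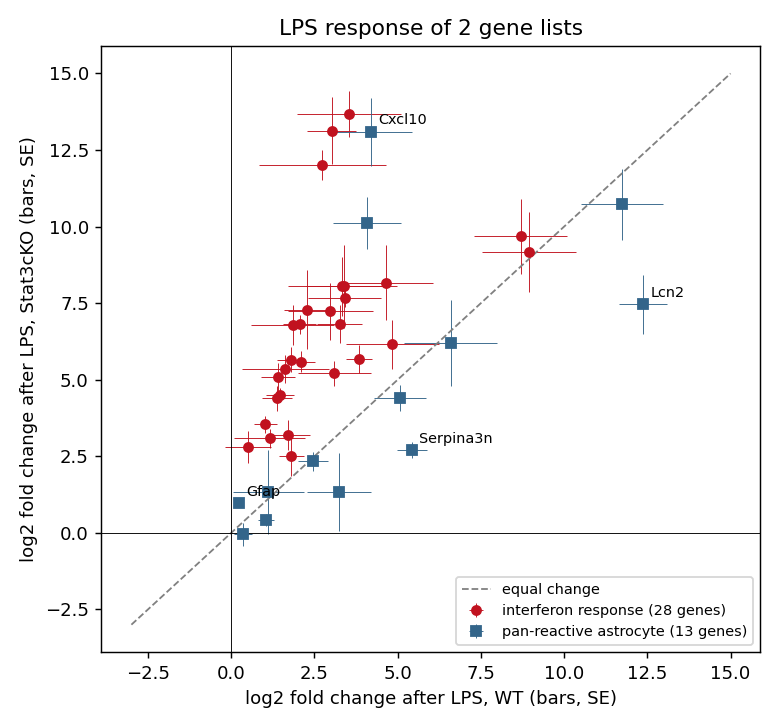
Log2 fold change after LPS (points, with SE) of interferon response and pan-reactive genes in WT (x axis) and Stat3cKO (y axis), with a dashed line of equal change. Over the genes tested in both, the median of the interferon list (28 genes) is 2.51 in WT and 6.48 in Stat3cKO, and that of the pan-reactive list (13 genes) 4.08 and 2.71.

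The largest falls of the difference were in genes at 0 or 1 counts in each uninjured WT library. Slc14a2, a urea transporter gene, had 0 counts in all of them and 449, 260, 522 and 869 after LPS (difference log2 -12.71 ± 1.96, adjusted p = 0.0115). Frem2 had 0, 0, 1 and 0 counts and then 397, 782, 772 and 352 (-11.85 ± 2.35), and the cannabinoid receptor gene Cnr1 had 0, 1, 0 and 0 and then 144, 386, 281 and 1877 (-11.51 ± 2.10). Further lists passed camera for the difference and lost it with an estimated correlation: cytokines (1 of 6; 2 over the list alone; adjusted p = 0.0537), complement (0 of 10; 2 over the list alone, 0.0537), NF-kB (0 of 13, 0.515), transcription factors (1 of 34, 0.515), glucocorticoid-responsive genes (0 of 22, 0.405) and oligodendrocyte markers (0 of 14, 0.585), all pointing up in Stat3cKO. Camera calls for NF-kB, transcription factors and oligodendrocytes were also lost without 1 library, in 9, 5 and 5 fits (adjusted p up to 0.219, 0.152 and 0.191). The pan-reactive list had 1 gene higher and 2 lower of 13 (median log2 -0.49, mean 0.21; camera 0.634). Microglia markers did not pass (0 of 3; median 0.16, test pointing down; 0.975). In all, 31 genes rose more and 8 less in Stat3cKO of 10341 tested, with 960 at an unadjusted p under 0.05. The count was 15 without Stat3cKO LPS 1, 15, 19 and 14 without Stat3cKO uninjured 1, 2 and 3, 119 without WT LPS 3 and 60 without WT uninjured 4, and it was 1 with all libraries in one fit. Of the 8 named genes past the threshold, Ifit1 and Slc14a2 held without any 1 library, Frem2 was lost in 11 fits (up to 0.0805) and Cnr1 in 3 (0.0578).

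The LPS responses of Smarca4cKO and WT were also compared. Lcn2, Serpina3n, Gfap, Vim and Cxcl10 did not pass: the difference was log2 -0.62 ± 0.74 for Lcn2 (adjusted p = 1), -1.55 ± 0.52 for Serpina3n (0.556), 0.50 for Gfap (0.761), 0.12 for Vim (1) and 9.89 ± 3.26 for Cxcl10 (0.525). Genes with the largest differences past the threshold were all-or-none in Smarca4cKO, where loss of molecules is not excluded. Gpx8, an endoplasmic reticulum peroxidase gene, had 0 counts in the uninjured libraries and 2280, 2073 and 2176 after LPS (14.77 ± 1.49, adjusted p = 0.00174), against 28.3 and 17.0 CPM in WT. Spata5l1 had 0 counts and then 2343, 652 and 1697 (12.77 ± 2.10), and Focad 1, 1 and 0 and then 1579, 2382 and 1317 (11.54 ± 1.79). In the other direction, Angel1 had 1582, 1629 and 4274 counts and then 0, 1 and 0 (-12.83 ± 1.92), Swsap1 1000, 1613 and 2565 and then 0, 0 and 1 (-12.10 ± 1.94), and Cercam 1364, 1882 and 1924 and then 0, 1 and 1 (-11.33 ± 1.85). Other genes named in every comparison were at 0.11 (Stat3), -0.14 (Smarca4), 0.28 (C3), 0.43 (Aqp4) and 0.16 (Slc1a2), each with an adjusted p of 1. Genes of antigen presentation and of the A1 type passed camera pointing up, each with 1 gene past the threshold (of 11 and 9; 1 and 2 over the list alone), and lost the call with an estimated correlation (adjusted p = 0.555 each). Both lost it also without Smarca4cKO uninjured 3 (0.0778 and 0.166) and LPS 1 (0.125 and 0.277), and the A1 type without WT LPS 4 (0.0542). In all, 14 genes rose more and 11 less of 7919 tested, with 376 at an unadjusted p under 0.05. The count was 115, 49 and 73 without Smarca4cKO uninjured 1, 2 and 3, 367 without Smarca4cKO LPS 3, 14 without WT LPS 2, 15 without WT uninjured 4 and 1 by limma voom. Of the 6 named genes past the threshold, Spata5l1 was lost without WT LPS 1, WT LPS 2 and WT uninjured 4 (up to 0.0656).

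The LPS responses of Smarca4cKO and Stat3cKO were compared in the same way. Lcn2 and Serpina3n differed by log2 4.36 ± 1.00 (adjusted p = 0.0723) and 1.25 ± 0.30 (0.0839), not past the threshold, as did Aqp4 (0.91, 0.132), Stat3 (-2.30, 0.368), Vim (0.82, 0.416), Slc1a2 (0.44, 0.44), C3 (-0.79, 0.958), and Gfap, Smarca4 and Cxcl10 (-0.17, 0.26 and 1.04, each 0.997). Gpx8 (14.67 ± 1.70, adjusted p = 0.00552), Spata5l1 (13.80, 0.0199) and Fnip2 (13.49, 0.0107), with 0 counts uninjured and 1227, 1756 and 2342 after LPS in Smarca4cKO, led the rises. Swsap1 (-12.65, 0.00952), Cyb5r4 (-11.78, 0.0109; 1624, 1603 and 940 counts and then 0, 0 and 1) and the phosphatase gene Ptp4a1 (-12.73 ± 2.61, 0.0425; 1158, 2614 and 8 counts uninjured) led the falls. Homeostatic genes pointed up (3 higher and 1 lower of 35; 8 and 1 over the list alone; adjusted p = 0.667 with an estimated correlation), as did pan-reactive genes (0 of 13; 2 over the list alone, 0.213), ependymal markers (1 of 3, 0.141) and Schwann cell markers (0 of 5, 0.181), and complement genes pointed down (0 of 7, 0.213). These camera calls were lost without Smarca4cKO LPS 1 (complement 0.0578, pan-reactive 0.144, homeostatic 0.0578), LPS 3 (complement 0.117, ependymal 0.0565, Schwann cell 0.117), uninjured 2 (complement 0.0528) and uninjured 3 (pan-reactive 0.0594, homeostatic 0.0503). In all, 37 genes rose more and 30 less of 7992 tested, with 587 at an unadjusted p under 0.05. The count was 178 and 133 without Smarca4cKO uninjured 1 and 3, 466 without Smarca4cKO LPS 3, 38, 32, 42 and 34 without Stat3cKO LPS 1 to 4, and 30, 15 and 20 without Stat3cKO uninjured 1 to 3. Gpx8 and Fnip2 held without any 1 library, Spata5l1, Swsap1 and Cyb5r4 were lost without Stat3cKO uninjured 2 and 3 (up to 0.0595, 0.0560 and 0.0610) and Ptp4a1 in 10 of 13 fits (up to 0.154).

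The difference between SCI and LPS in Smarca4cKO asks how a lesion and systemic inflammation diverge in these mice. LPS library 2 held 50.9 CPM of Smarca4, against 12.2 to 22.6 CPM in the SCI libraries, and the count of called genes without it was 245. Homeostatic genes were lower after SCI than after LPS in 19 of 35 cases and higher in 1 (24 and 4 adjusted over the list alone; adjusted p = 0.0721 with an estimated correlation). Slc1a2 differed by log2 -1.50 ± 0.22 (4374 ± 1229 and 12395 ± 1068 CPM, adjusted p = 0.0042), while Aqp4 was higher after SCI (4209 ± 501 and 2351 ± 246 CPM, 0.85 ± 0.13, adjusted p = 0.00603) and so was Vim (1523 ± 183 and 709 ± 156 CPM, 1.11 ± 0.19, 0.0104). Cholesterol synthesis genes were lower in 7 of 22 cases (12 lower and 1 higher over the list alone, 0.0721) and glucocorticoid-responsive genes in 4 of 20 (10 over the list alone, 0.0721). Oligodendrocyte markers were higher after SCI in 6 of 13 cases (11 over the list alone, 0.0721), progenitor markers in 1 of 7 (3 over the list alone, 0.09) and fibroblast markers in 1 of 4 (2 over the list alone, 0.143). Camk2n1, an inhibitor of the kinase CaMKII, differed by -3.15 ± 0.33 (102 ± 37.6 and 905 ± 250 CPM), Itih3 by -2.71 ± 0.34 (306 ± 144 and 2020 ± 320 CPM) and the stress gene Gadd45b by -3.07 ± 0.66 (29.2 ± 15.2 and 247 ± 195 CPM). Genes with no or almost no counts after LPS led the rises: Tmem8 (adjusted p = 0.0211), Ptp4a1 (11.84 ± 2.39) and Angel1 (11.77 ± 1.65). Not past the threshold were Lcn2 (-1.30, adjusted p = 0.139), Serpina3n (-0.37, 0.455), Gfap (-0.12, 0.913), Stat3 (-0.32, 0.944), Smarca4 (-0.05, 0.998), Cxcl10 (-3.27, 0.539) and C3 (0.64, 0.221). In all, 112 genes were higher and 189 lower after SCI of 7969 tested, with 1038 at an unadjusted p under 0.05. The count was 171, 166, 178 and 159 without SCI 1 to 4 and 763 without Smarca4cKO LPS 3. Calls lost without 1 library were those of Tmem8 (SCI 2, 3 or 4, up to 0.0608), Ptp4a1 (5 of 10 fits, 0.0610), Gadd45b (5, 0.131) and the fibroblast list (LPS 1 and LPS 3, 0.0571 and 0.0629).

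The overlap of calls bears on whether the challenges change the same genes. WT and Stat3cKO shared 96 genes that rose after LPS and 43 that fell, where independent calls among 10341 genes would share 10.2 and 3.83, and 0 genes moved in opposite directions. Of 145 genes that rose in WT, 138 were higher in Stat3cKO (median log2 1.77 in WT and 1.44 in Stat3cKO), and of 104 that fell, 100 were lower (-1.13 and -0.75). Of 124 genes that rose in WT and were tested in Smarca4cKO, 113 were higher there after LPS (1.63 and 1.39), and 88 of 101 that fell were lower (-1.13 and -0.53). Of 648 genes that rose in Stat3cKO, 494 were higher in Smarca4cKO after LPS (1.34 and 0.57), and 274 of 368 that fell were lower (-1.03 and -0.37). The 2 genes called in Smarca4cKO after LPS, Lcn2 and Serpina3n, rose in all 4 challenge comparisons. WT after LPS and Smarca4cKO after SCI shared 40 rises and 32 falls, where 8.30 and 5.00 would be shared independently, with 6 and 4 in opposite directions. Stat3cKO after LPS and Smarca4cKO after SCI shared 101 rises and 89 falls (54.3 and 17.6), with 36 up after LPS and down after SCI, 19 the other way, and 62.0 opposite pairs when independent. The Smarca4cKO responses to LPS and SCI share 3 uninjured libraries, so their fold changes correlate even without a common response. Pearson's r across genes, which are not independent replicates, was 0.710, where 100 simulations of unchanged groups gave a mean of 0.543 and at most 0.571. The simulated libraries were all drawn from the uninjured means, so genes with almost no uninjured counts stayed low in every group. The real all-or-none genes are not reproduced in this way, so the excess of r does not show a common response. The shares of genes with the same sign were 69.0% and, in the simulations, up to 69.2%.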

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

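Tests chosen only after the result was seen were those of library depth after SCI, of microglia and macrophage RNA, and of interferon genes lost from WT libraries, and the limits used for a smaller response in Smarca4cKO and for the uninjured level in Stat3cKO were tightened after their values were seen.

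Interferon genes rose more after LPS in Stat3cKO than in WT, by a median log2 of 3.53 over 28 genes. RNA of microglia and macrophages in the Stat3cKO LPS libraries stays open. Their 9 markers had a median of 9.95 CPM (3.90 for Tyrobp to 45.9 for Sall1). The 32 interferon genes called had a lower quartile of 108 CPM but were chosen by their rise there, so this cannot decide. Cd68 (log2 8.65) and Olfml3 (3.47), named after their values were seen, rose there. A lower level before LPS is argued against as the main cause only by the estimate, an uninjured difference of median log2 -0.43 beside 3.53 for the responses. Its 95% bootstrap interval (-0.85 to -0.12) resampled the 28 genes, not the mice, so it holds no spread between animals and cannot decide the question. In addition, 20 of 28 genes were lower in uninjured Stat3cKO, and the interval comes close to the limit of 0.25 times the difference of responses. Loss of interferon genes from WT LPS libraries is argued against for the 14 genes with over 10 counts in every uninjured WT library, 0% of which had 10 counts or fewer in any of them, and cannot be told apart from a smaller rise for the other 14, whose 0% follows from filters that keep such genes for their counts after LPS. Loss of Stat3 itself remains a candidate explanation, although Stat3 reads rose after LPS in Stat3cKO (log2 3.85 ± 0.51, to 174 CPM against 118 CPM in uninjured WT, a difference not tested), and other differences between the mouse lines stay open, as does sex, which the labels do not give.

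After SCI, 828 genes rose from 10 counts or fewer in every uninjured Smarca4cKO library. The highest SCI total was 1.48 times the lowest uninjured total, below the lowest rise in counts (48.8-fold, with 0 set at 3). Genes were chosen by their rise, so this cannot decide on depth. Loss of molecules from the uninjured Smarca4cKO libraries cannot be told apart from the lesion as the whole cause: of 314 such genes in the WT table, 228 (72.6%) had over 10 counts in at least 3 of 4 uninjured WT libraries, but 514 are not in that table, and the WT mice differ in genotype and strain. Of the 314, 11 had 10 counts or fewer in every uninjured WT library. The 228 genes had a median of 7.07 CPM in uninjured WT, close to the median of 7.80 CPM of all 828 genes after SCI. No biological explanation was tested for these genes.

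In Smarca4cKO 2 genes passed the test after LPS, and 5 without LPS library 1. Group size could account for much of this, since choices of 3 against 3 WT libraries gave as few as 8 calls (median 26.5, highest 205, 16 choices), though the test made calls at this size on simulated data. A wider spread between libraries with the folds kept could add to it: over 645 genes called higher in Stat3cKO and tested in both, the median fold in Smarca4cKO was 0.841 times that in WT on the log2 scale (0.56 and 0.66), and the median SE was 0.716 against 0.364. This covers rises only. Genes called in WT had medians of log2 1.63 in WT and 1.39 in Smarca4cKO for rises, but -1.13 and -0.53 for falls. Falls were thus kept less, although these genes were chosen by their WT calls. A smaller response without Smarca4 is not settled, since 4 of 225 genes called in WT (1.78%, 95% interval 0.486 to 4.49) responded less in Smarca4cKO when adjusted over these genes. The deletion is also confounded with strain, which the labels give as mixed for Smarca4cKO alone, and LPS library 2 held 50.9 CPM of Smarca4, close to the lowest WT library at 59.4 CPM (2 calls without it).

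Other splits of the same libraries were counted for each comparison. The real split alone, 1 of 35, gave as many calls for WT (268) and Stat3cKO (1237) after LPS and Smarca4cKO after SCI (1606), highest other 0. Other splits mix treated and untreated mice, and 35 are too few to exclude chance over several comparisons. For Smarca4cKO after LPS the 10 splits are too few for a share under 0.05 (2 calls, highest other 0). Among the differences, SCI minus LPS gave 301 calls (1 of 35 splits, highest other 0). For differences between genotypes, the splits exchanged genotype labels within each treatment. This also mixes any difference between uninjured genotypes into the groups, so these splits cannot exclude chance for a difference of responses. As many calls as in the real split, itself included, came from 1 of 100 splits for Smarca4cKO minus Stat3cKO (67 calls, highest other 41). They came from 3 of 100 for Stat3cKO minus WT (39, highest other 42) and 2 of 100 for Smarca4cKO minus WT (25, highest other 25).

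Some libraries lay apart from the others of their group, with a gap to the nearest that was a large part of the group's range. This held in 18 of 224 groups of values (8.04%), where chance gives about 1 in 20. Library 3 of WT LPS was apart for Cxcl10 (gap 0.946 of the range), Tgm1 (0.910), Cdkn1a (0.905), Gbp5 (0.900) and, on the low side, Sall1 (0.844). In uninjured WT, library 4 was apart for Socs3 (0.969), Timp1 (0.906) and Lrg1 (1.0), and library 1 for Col1a1 (0.906) and H2-Q4 (0.904). Library 2 of uninjured WT was apart for Clcf1 (1.0), Olig1 (0.901, low), Col1a2 (0.859) and Vim (0.858). In Stat3cKO LPS, library 4 was apart for Hes5 (1.0). Library 4 of SCI was apart for Fam101a (0.953), Aqp4 (0.918) and Lif (0.842). The ratios of 1.0 set 0.0113 CPM of Clcf1, 0.0241 CPM of Lrg1 and 0.0125 CPM of Hes5 against 0 in the other libraries.

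These differences of responses passed the test, in log2 units. For Stat3cKO minus WT these were Ifi44 (10.105), Ifit1 (10.08), Cxcl10 (8.86), Serpina3n (-2.75), Lcn2 (-4.95), Cnr1 (-11.51), Frem2 (-11.85) and Slc14a2 (-12.71). Smarca4cKO minus WT gave Gpx8 (14.77), Spata5l1 (12.77), Focad (11.54), Cercam (-11.33), Swsap1 (-12.10) and Angel1 (-12.83). Smarca4cKO minus Stat3cKO gave Gpx8 (14.67), Spata5l1 (13.80), Fnip2 (13.49), Cyb5r4 (-11.78), Swsap1 (-12.65) and Ptp4a1 (-12.73). For SCI minus LPS they were Tmem8 (12.0002), Ptp4a1 (11.84), Angel1 (11.77), Vim (1.11), Aqp4 (0.85), Slc1a2 (-1.50), Itih3 (-2.71), Gadd45b (-3.07) and Camk2n1 (-3.15). Values beyond 10 in size come from genes at or near 0 counts in a group and are not bounds. In Smarca4cKO loss of molecules is not excluded for them.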

How the results depend on the processing

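Tests chosen only after the result was seen were robust quasi-likelihood, limma voom and a mean of at least 20 CPM. Values below are in the order WT, Stat3cKO and Smarca4cKO after LPS, Smarca4cKO after SCI, Stat3cKO minus WT, Smarca4cKO minus WT, Smarca4cKO minus Stat3cKO and SCI minus LPS, and the cause of a change was not tested unless given. The genes called numbered 268, 1237, 2, 1606, 39, 25, 67 and 301, and 613, 1730, 288, 2383, 166, 100, 210 and 735 by DESeq2, whose calls on simulated data held 27.6%, 34.0%, 59.5% and 56.0% unchanged genes in the single comparisons. The likelihood ratio test gave 520, 1617, 149, 1730, 123, 73, 132 and 417, and all libraries in one fit, which tests the genes that all tables list, 238, 356, 278, 768, 1, 73, 110 and 654. Median-of-ratios gave 250, 1217, 2, 1602, 39, 23, 64 and 308, and no low-count filter 270, 1230, 2, 1605, 39, 25, 67 and 301. The stricter null of a fold over 2 left 18, 296, 2, 979, 8, 20, 33 and 43. The authors' FDR gave 542, 1621, 174 and 1724 in the single comparisons. Robust quasi-likelihood gave 289, 1227, 6, 1600, 21, 21, 67 and 302, limma voom 264, 1249, 73, 1418, 16, 1, 44 and 468, and a mean of at least 20 CPM, with fewer genes tested, 377, 1388, 6, 655, 58, 3, 8 and 292. Lists called numbered 14, 16, 14, 21, 9, 2, 5 and 6, with an estimated correlation 3, 7, 2, 8, 3, 0, 0 and 0, and by fry 11, 17, 3, 24, 5, 0, 5 and 7. Calls shared at an adjusted p under 0.01 fell to 10 for WT and Stat3cKO LPS, 6 for WT LPS and SCI, and 69 for Stat3cKO LPS and SCI, from 139, 72 and 190, by the stricter threshold. Leaving out 1 library gave 29 to 217, 657 to 1275, 2 to 5, 1293 to 2266, 14 to 119, 14 to 367, 15 to 466 and 159 to 763 genes, and 12 to 15, 15 to 16, 12 to 16, 18 to 22, 6 to 10, 0 to 7, 3 to 6 and 5 to 9 lists. The counts that moved by over 1.5 times, follow in parentheses after the library left out. For genes in WT LPS, without WT LPS 2 (29), WT LPS 3 (176), WT LPS 4 (122), WT uninjured 1 (141), WT uninjured 3 (58) and WT uninjured 4 (68). For genes in Stat3cKO LPS, without Stat3cKO uninjured 1 (657), Stat3cKO uninjured 2 (748) and Stat3cKO uninjured 3 (692). For genes in Smarca4cKO LPS, without Smarca4cKO LPS 1 (5). For genes in Stat3cKO minus WT, without Stat3cKO LPS 1 (15), Stat3cKO uninjured 1 (15), Stat3cKO uninjured 2 (19), Stat3cKO uninjured 3 (14), WT LPS 3 (119) and WT uninjured 4 (60). For genes in Smarca4cKO minus WT, without Smarca4cKO uninjured 1 (115), Smarca4cKO uninjured 2 (49), Smarca4cKO uninjured 3 (73), Smarca4cKO LPS 3 (367), WT LPS 2 (14) and WT uninjured 4 (15). For lists in Smarca4cKO minus WT, without Smarca4cKO uninjured 2 (4), Smarca4cKO uninjured 3 (0), Smarca4cKO LPS 1 (0), Smarca4cKO LPS 3 (6), WT LPS 3 (7), WT LPS 4 (1), WT uninjured 1 (5) and WT uninjured 2 (4). For genes in Smarca4cKO minus Stat3cKO, without Smarca4cKO uninjured 1 (178), Smarca4cKO uninjured 3 (133), Smarca4cKO LPS 3 (466), Stat3cKO LPS 1 (38), Stat3cKO LPS 2 (32), Stat3cKO LPS 3 (42), Stat3cKO LPS 4 (34), Stat3cKO uninjured 1 (30), Stat3cKO uninjured 2 (15) and Stat3cKO uninjured 3 (20). For lists in Smarca4cKO minus Stat3cKO, without Smarca4cKO uninjured 3 (3), Smarca4cKO LPS 1 (3) and Smarca4cKO LPS 3 (3). For genes in SCI minus LPS, without Smarca4cKO SCI 2 (166), Smarca4cKO SCI 3 (178), Smarca4cKO SCI 4 (159), Smarca4cKO SCI 1 (171) and Smarca4cKO LPS 3 (763). Of the named genes past the threshold (36, 54, 2, 56, 8, 6, 6 and 9), DESeq2 kept 36, 54, 2, 56, 8, 6, 6 and 6, with no value for 3 of the last 9 and no call lost. All libraries in one fit gave a value for 22, 32, 2, 32, 3, 6, 4 and 9 of them and kept 14, 24, 2, 28, 1, 6, 4 and 9. Of the full numbers limma voom kept 15, 26, 2, 51, 0, 1, 5 and 8, and every fit without 1 library 11, 36, 2, 50, 2, 5, 2 and 6. The sign changed in 173 of 7347 values of named genes and lists, 155 of them without 1 library, and 0 of the 173 were past the threshold in either fit. Outside the fits without 1 library these were, by fry, the WT lists of microglia (adjusted p = 0.918) and ependymal cells (0.908), heat shock in Stat3cKO (0.723), BAF complex (0.332) and heat shock (0.276) after SCI, A1-type in Smarca4cKO minus Stat3cKO (0.991) and pan-reactive in SCI minus LPS (0.832). By median-of-ratios they were cholesterol in Smarca4cKO minus WT (0.993) and Smarca4 in Smarca4cKO LPS (log2 0.02996, and 0.02996 by DESeq2). By limma voom they were Sall1 (-0.0301) and Smarca4 (-0.00732) in WT, Pecam1 after SCI (1.07), Stat3 in Smarca4cKO minus WT (-0.0477), Smarca4 (-2.83) and Cxcl10 (-4.68) in Smarca4cKO minus Stat3cKO, and Smarca4 (3.13) and Cxcl10 (3.10) in SCI minus LPS. Without 1 library 68 results changed sign, with these ranges of adjusted p (lists) and log2 (genes). In WT LPS matrix 0.551 to 0.999, heat shock 0.405 to 0.971, microglia 0.485 to 0.995, ependymal 0.711 to 0.995 and Schwann cell 0.134 to 0.735, with log2 Sall1 -0.10 to 0.33, Thy1 -0.0452 to 0.21, Smarca4 -0.17 to 0.18 and Slc1a2 -0.12 to 0.0495. In Stat3cKO LPS heat shock 0.842 to 0.993, microglia 0.773 to 0.993, oligodendrocyte 0.769 to 0.969, pericyte 0.699 to 1.00 and ependymal 0.839 to 0.993, with log2 Pdgfrb -0.59 to 0.14. In Smarca4cKO LPS homeostatic 0.450 to 0.987, cell cycle 0.887 to 0.996, BAF complex 0.703 to 0.996 and axon growth 0.559 to 0.960, with log2 Col1a2 -0.31 to 0.15, Foxj1 -1.38 to 0.0754 and Smarca4 -2.69 to 0.55. In SCI heat shock 0.207 to 0.663 and neuron 0.0815 to 0.973, with log2 Smarca4 -0.36 to 0.0380. In Stat3cKO minus WT pan-reactive 0.105 to 0.988, A2-type 0.748 to 0.987, homeostatic 0.364 to 0.994, cholesterol 0.160 to 0.988, heat shock 0.537 to 0.994, microglia 0.713 to 0.994, neuron 0.713 to 1.00, pericyte 0.537 to 0.988 and Schwann cell 0.0861 to 0.978, with log2 Socs3 -5.73 to 0.23. In Smarca4cKO minus WT cytokines 0.640 to 0.998, cholesterol 0.510 to 0.998, cell cycle 0.613 to 0.975, transcription factors 0.354 to 0.999, oligodendrocyte 0.288 to 0.998, progenitor 0.103 to 0.860 and fibroblast 0.609 to 0.959, with log2 Stat3 -0.61 to 0.38, Smarca4 -2.79 to 0.46, Vim -0.15 to 0.30 and Lcn2 -0.91 to 0.10. In Smarca4cKO minus Stat3cKO A1-type 0.668 to 0.999, antigen presentation 0.114 to 0.893, STAT3 targets 0.342 to 0.995, glucocorticoid-responsive 0.0578 to 0.957, cholesterol 0.273 to 0.959, cell cycle 0.741 to 0.989, transcription factors 0.129 to 0.952, BAF complex 0.672 to 0.986, progenitor 0.246 to 0.967 and fibroblast 0.469 to 0.923, with log2 Smarca4 -2.43 to 0.85 and Cxcl10 -6.84 to 2.20. In SCI minus LPS pan-reactive 0.529 to 0.937, A2-type 0.375 to 0.989, interferon 0.0354 to 0.835, cytokines 0.626 to 0.989, STAT3 targets 0.275 to 0.995, transcription factors 0.239 to 0.752 and BAF complex 0.686 to 0.995, with log2 Stat3 -0.59 to 0.44, Smarca4 -0.61 to 2.63 and Cxcl10 -3.85 to 4.64. The interferon list in SCI minus LPS passed without Smarca4cKO LPS library 2 (0.0354). Alternatives planned for normalized values were not run, since the tables hold counts. Few counts limit the folds after SCI, where 828 of 1127 rises start from 10 counts or fewer in every uninjured library, and on simulated data 58%, 58%, 20% and 29% of 8-fold changes were recovered in the single comparisons.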

Other observations

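The genes below were chosen after their values were seen, and no tests between uninjured groups are reported for them. In astrocytes of uninjured cords, with each group scaled within its own table, the filament gene Gfap was at 18232 ± 2735 CPM in WT (n = 4), 4954 ± 238 in Stat3cKO (n = 3) and 15305 ± 224 in Smarca4cKO (n = 3, SCI table). Complement C3 was at 568.1 ± 227, 66.7 ± 17.2 and 493 ± 54.1 CPM, and Vim at 251 ± 85.7, 153 ± 16.7 and 320 ± 76.3. The astrocyte enzyme gene Aldh1l1 was at 491 ± 70.9, 500.4 ± 13.3 and 389 ± 57.01 CPM, and the transcription factor gene Sox9 at 311 ± 46.5, 328 ± 10.1 and 226 ± 10.1. The glutamate transporter gene Slc1a3 was at 896 ± 271, 964 ± 88.0 and 710 ± 127 CPM before treatment. After SCI it fell to 391 ± 95.9 (log2 -0.86 ± 0.22, edgeR adjusted p = 0.0325), and alternatives were not run for this gene. After LPS it was at 811 ± 138 in WT (log2 -0.14, adjusted p = 0.878 by edgeR) and 951 ± 127 in Stat3cKO (-0.02, adjusted p = 0.957 by edgeR). The values after ± are SDs over libraries for CPM and SEs for log2.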
